A study of Mus musculus with 9 samples.

How the data were processed

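Endothelial RNA was measured on 9 mouse Clariom D arrays (the renamed Mouse Transcriptome Array), which cover coding and non-coding transcripts, 4 from control and 5 from ACDiEKO mice, with 1 thoracic aorta per array. Per the labels, each RNA (5 ng) was amplified with the WT Pico protocol. The deposited values are log2 values that the authors made with RMA (no version given, per the submitters' processing notes), a method that corrects background, normalizes arrays and summarises probes to 1 value per transcript cluster. They ran from 2.58 to 19.34. A 16-bit scanner spans 16 log2 units, so a further scaling step that the notes do not state was applied, and differences are given as log2 units of the deposited values and never as folds. The genome build and annotation are not stated, and no coordinates are printed. For arrays, their number limits the precision.

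Of 72688 features, 6732 array controls were left out, which left 65956 transcript clusters. Of these, 32750 were in the array's table of names, 30604 with 1 symbol and 2146 with several, and 33206 had no symbol listed. Through gene IDs, 827 symbols were updated to those of the GRCm38 RefSeq table, which served for names and for the order of neighbouring genes only. Clusters with 1 symbol were collapsed to the brightest cluster per symbol, which gave 30142 genes. A gene was tested where at least 4 arrays lay above the median of all values in the table (6.165), which left 16403.

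The titles give 2 control arrays the number 3, and the second is called control replicate 4 here. ACDiEKO replicates 1 and 2 were nearly identical and were averaged, so 8 samples were fitted. This departs from the plan, which counted 9 arrays, and was chosen after seeing the data. The numbers after "rep" were checked as a pairing: the correlations across genes of deviations from group means between arrays of the same number were -0.0049, -0.145, 0.0353 and 0.0413, so the numbers do not pair the arrays.

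Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, ACDiEKO minus control) with Benjamini-Hochberg adjustment at 0.05, two-sided. Unless another fit, test or setting is named, adjusted p-values come from this limma fit or, for gene lists, from its function camera (preset correlation 0.01). Those of lists were adjusted over the 42 lists with at least 3 tested members. The comparison, the 31 gene lists and 13 marker lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the MEF2 family, the 12 largest rises and 12 largest falls among genes past the threshold whose arrays do not overlap (gene models, small RNAs, olfactory and similar receptors and immunoglobulin segments left out), the 3 members of each list with the smallest p (up to 5 where more passed), and 18 genes fixed by name. Other genes are said to have been chosen after their values were seen.

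The steps were tested on simulated data of the same size. In 5 runs, 200 of 16403 genes were changed. Limma recovered 78.8% of genes changed by 1 log2 unit and 94.4% of those changed by 2, with 6.07% false calls. Camera called 5 of 5 planted lists and 0 of 150 others. Genes were simulated independently of each other, so these runs do not check camera on lists of correlated genes. In the data, the estimated correlation within the cell cycle list was 0.633. Alternatives tried were other thresholds, no filter and a stricter filter (75th percentile, 8.417), median centring, quantile normalization, the mean of a gene's clusters, an intensity trend with robust variance, array weights, the replicate numbers as a block, the animal numbers, smooth muscle and erythrocyte marker means as covariates, leaving out each array, an estimated correlation, fry and camera on ranks. Added after seeing the data were all 9 arrays as samples and a fit without both near-identical arrays. Schwann cell and erythrocyte markers had too few tested members for camera, and Mef2b lies only on clusters that name several symbols, so these were left out. Figures were drawn with matplotlib.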

Results

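Gene expression was measured in the endothelial layer of the mouse thoracic aorta, the inner lining that faces the flowing blood. MEF2A, MEF2C and MEF2D are transcription factors of the MEF2 family. ACDiEKO mice carried floxed Mef2a, Mef2c and Mef2d together with Cdh5-CreERT2, a recombinase that is active in endothelial cells and switched on by tamoxifen. Controls were littermates that lacked the recombinase and received the same tamoxifen. All mice were female, were 10 weeks old at tamoxifen, and received 5 daily injections. The series text places the harvest 7 days after the first injection and the sample protocols place it 14 days after, and the time is not settled here. RNA was collected by flushing lysis reagent through the lumen of individual aortas, and 5 ng of each RNA was hybridised to a whole-transcriptome mouse array. The series holds 9 arrays, 4 from control and 5 from ACDiEKO, with 1 aorta per array. Array medians of the deposited values (log2) lay between 6.17 and 6.23 in controls and between 6.13 and 6.15 in ACDiEKO, without overlap. The number of arrays limits the precision.

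ACDiEKO replicates 1 and 2 were almost the same array result. The robust SD of their difference over bright features was 0.0755, against 0.283 to 0.471 for the other 15 pairs of arrays from the same group, and their correlation across features was 0.997, against 0.985 to 0.990. Over dim features the robust SD was 0.103, against 0.110 to 0.153. Both arrays were averaged and counted as 1 sample, so 4 ACDiEKO samples were compared with 4 control samples.

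**Figure D1:**
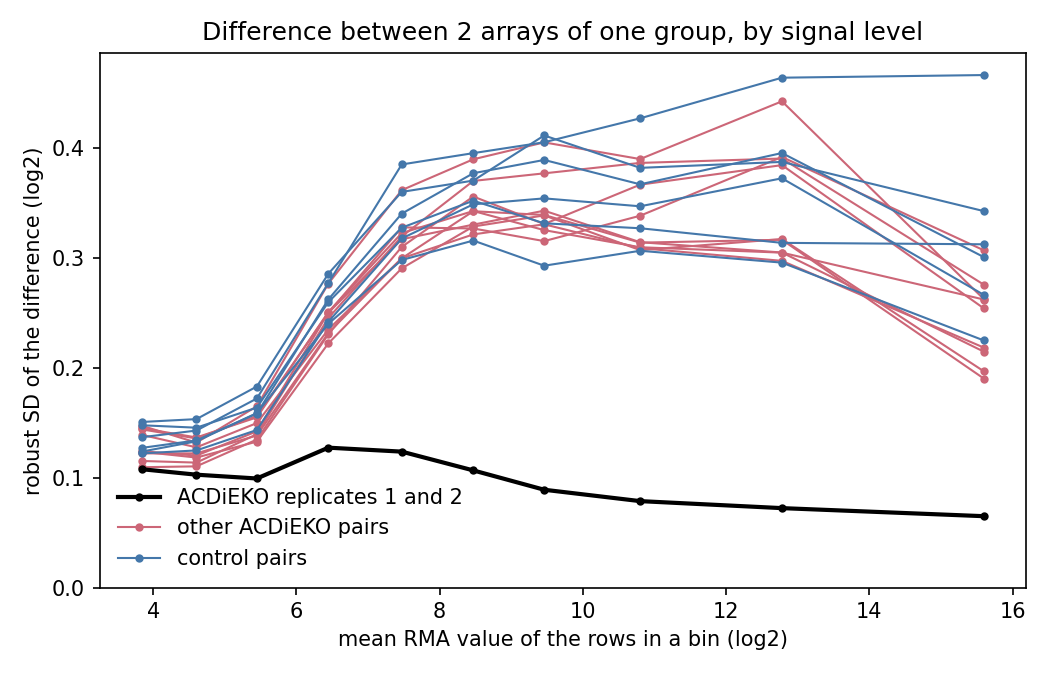
Robust SD of the difference between 2 arrays of one group (vertical axis, log2) against the mean RMA value of the features in a bin (horizontal axis, log2), with 1 line per pair of arrays. The black line, ACDiEKO replicates 1 and 2, lies below all 15 other lines; over bright features it was 0.0755 and the others lay between 0.283 and 0.471.

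The 3 floxed genes were read first, in a limma fit of all 30142 named genes with no filter on dim genes. Mef2a was 13.64 ± 0.10 in control and 13.76 ± 0.18 in ACDiEKO (SD, n = 4 and 4; array range 13.55 to 13.76 against 13.61 to 13.98), a log2 difference of 0.12 (limma, adjusted p = 0.493). Mef2c was 9.90 ± 0.09 and 9.96 ± 0.11 (array range 9.78 to 9.99 against 9.86 to 10.12), a difference of 0.06 (adjusted p = 0.663). Mef2d was 10.29 ± 0.10 and 10.53 ± 0.13 (array range 10.15 to 10.38 against 10.42 to 10.68), a difference of 0.23 (adjusted p = 0.144), and it passed after quantile normalization (0.31, adjusted p = 0.0375). None of the 3 was lower in ACDiEKO. Each value summarises probes along the whole transcript, which includes parts outside the exons removed by the recombinase, so these values do not check the genotype labels. Mef2b, the remaining family member, lies only on array features that name several symbols and is not reported. The 3 class IIa histone deacetylases tested, which bind MEF2 proteins and repress their targets, did not pass the test: Hdac4 differed by -0.28, Hdac7 by -0.18 and Hdac9 by -0.03. Camera gave adjusted p = 0.38 for the MEF2 family (median 0.12) and 0.401 for the deacetylases (median -0.18).

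The comparison of ACDiEKO with control asks which transcripts of the endothelial layer differ in mice made to lose the 3 MEF2 factors. Controls lacked the recombinase, so its own effect cannot be told apart from that of MEF2 loss, here or in any result below. Cell division genes were higher in ACDiEKO: Mki67, the proliferation marker, rose from 8.06 ± 0.28 to 13.74 ± 0.42 (log2, SD, n = 4 and 4), and all 32 measured genes of the cell cycle list rose. Of 21 tested genes of the laminar flow list, 14 fell and 7 did not pass, and its call ended with an estimated correlation (adjusted p = 0.527): Klf4 fell from 12.67 ± 0.11 to 8.58 ± 1.07, Klf2 from 10.90 ± 0.32 to 7.35 ± 0.79, and Nos3, the endothelial nitric oxide synthase, from 13.19 ± 0.29 to 10.95 ± 0.49. Edn1, the precursor of the vasoconstrictor endothelin-1, rose from 12.04 ± 0.96 to 14.71 ± 0.29, and Sele, the leukocyte adhesion molecule E-selectin, from 8.08 ± 1.15 to 13.53 ± 1.71. Of 14 smooth muscle markers tested, 8 rose, among them Acta2 (from 14.30 ± 1.30 to 17.49 ± 0.49), while Myh11 (-0.04), Cnn1 (-0.27) and Mylk (0.43) did not pass.

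**Figure D2:**
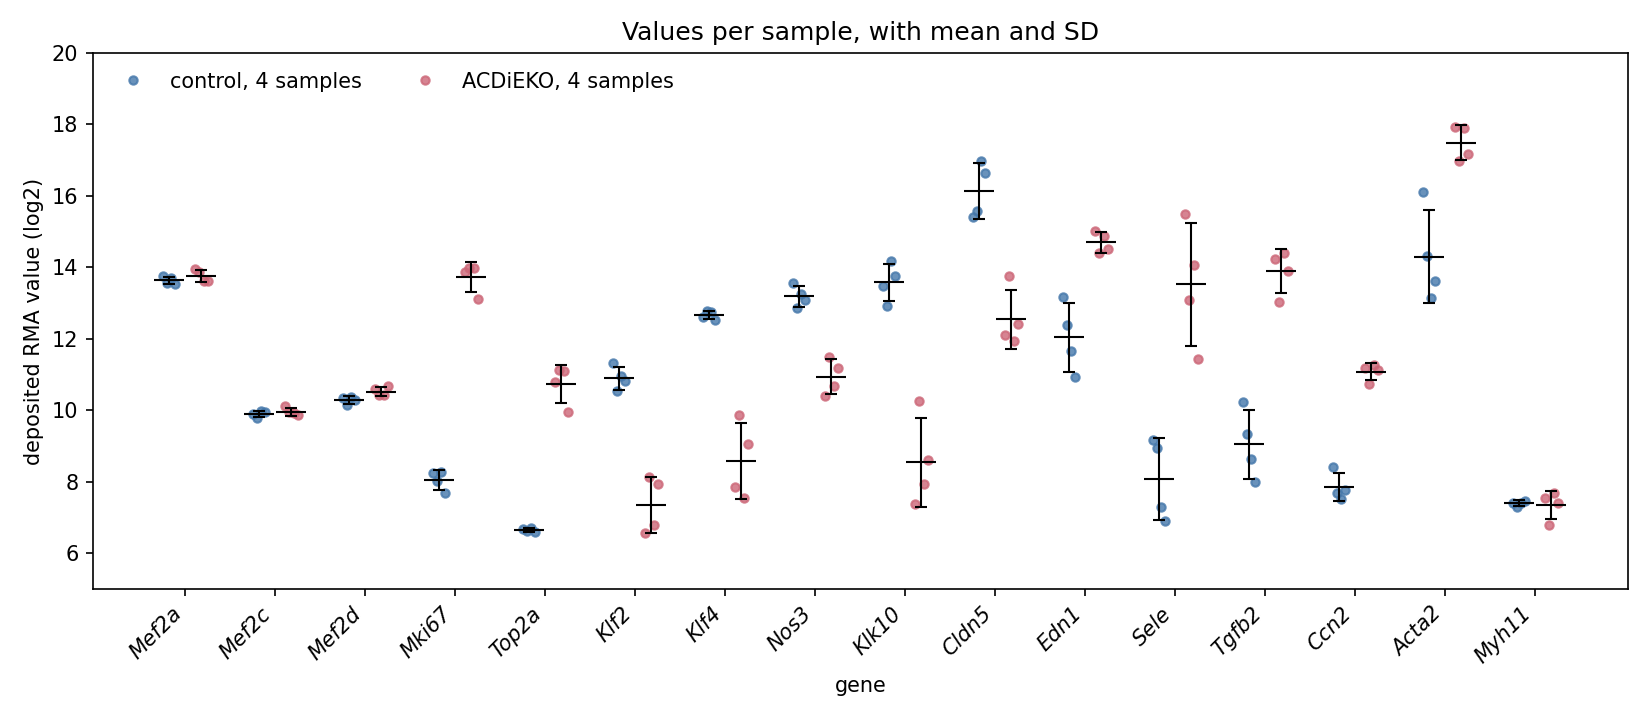
Deposited RMA value (vertical axis, log2) of 16 genes in the 4 control and 4 ACDiEKO samples; points are samples (ACDiEKO replicates 1 and 2 averaged to 1), and horizontal bars with whiskers are the mean and SD. The floxed genes Mef2a, Mef2c and Mef2d and the smooth muscle gene Myh11 differed by 0.12, 0.06, 0.23 and -0.04, while Mki67 differed by 5.68 and Klf4 by -4.09.

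Of 16403 genes tested, 2666 (16.3%) passed limma with Benjamini-Hochberg adjustment, 1463 higher and 1203 lower in ACDiEKO. The difference was at least 1 on the log2 scale in 874 of them, 502 higher and 372 lower. In 3777 of the 16403 tested genes, no control sample overlapped the ACDiEKO range, a separation that chance gives to 2.86% of genes. Over all 65956 transcript clusters, the array's features, 2824 passed, 1296 higher and 1528 lower, and 1023 of these (283 higher, 740 lower) carry no symbol in the annotation used here. Centring the arrays on their medians gave 1873 higher and 978 lower genes, and a further quantile normalization gave 2064 and 1024. The balance of higher and lower calls therefore depends on the scaling. Every control array had a higher median than every ACDiEKO array, an offset that centring removes. The count was 3710 with each of the 9 arrays as its own sample and 1127 without the 2 controls whose animal numbers lie apart. It was 1692 with the run of animal numbers as a term and 1680 (948 higher, 732 lower) without ACDiEKO replicate 4. With the mean of all smooth muscle markers, dim ones included, as a covariate in limma, it was 0. With the mean of the 14 tested markers as the covariate, limma gave 1397 genes at an unadjusted p under 0.05. The count of transcript clusters was 58 without the 2 controls whose animal numbers lie apart, 1234 with the run of animal numbers as a term, 1880 without control replicate 2, 1304 without control replicate 3, 1326 without control replicate 4 and 1134 without ACDiEKO replicate 4.

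Of the 12 largest rises, Mki67 rose by 5.68 (adjusted p = 7.52e-05), Sele by 5.44 (0.0061) and Tgfb2, a transforming growth factor ligand, by 4.84 (0.000926). Next came Top2a, the DNA topoisomerase of dividing cells (4.09), Ulbp1, a ligand of the NKG2D receptor (3.93), the actin-binding Tagln (3.82), the endothelial sialomucin Emcn (3.72) and the myosin light chain Myl9 (3.68). Ctla2a (3.58), the spindle motor Kif11 (3.54), the nuclear import adaptor Kpna2 (3.50) and the spindle protein Prc1 (3.49) completed the 12. The control mean of Kif11 (6.16) lay below the filter value of 6.165, so the size of its rise and its rank may be understated. That value is the median of the table and not a measured background. Ctla2a has a near-identical copy that its probes may not tell apart, so its value is uncertain.

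The largest falls included several kallikreins, secreted serine proteases of 1 gene cluster. Klk1b21 fell by 5.92 (adjusted p = 0.00283), Klk10 by 5.04 (0.00162), and Klk1 fell by 4.74 (0.0011). Klk1b24 fell by 4.26, Klk1b5 by 3.67 and Klk1b27 by 3.53. Klk1 and the Klk1b genes are near-identical copies, so single values among them are uncertain. The ACDiEKO means of Klk1b21 (6.06) and Klk1b27 (6.06) lay below the filter value of 6.165, so the sizes of their falls may be understated. The same holds for Fgl2 (ACDiEKO mean 5.96). Prrt4, a proline-rich transmembrane protein, fell by 4.44, the transcription factors Klf4 and Klf2 by 4.09 and 3.55, Pkhd1l1 fell by 3.75 and the tight junction protein Cldn5 fell by 3.59. Ly6c2, a surface antigen with a near-identical copy (Ly6c1), fell by 3.70 and is uncertain for that reason.

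All 32 measured genes of the cell cycle list rose, with a median log2 difference of 2.24 (32 rose and 0 fell adjusted over the list alone). Besides Mki67, Top2a, Prc1 and Kif11, the mitotic cyclins Ccnb2 (3.20) and Ccna2 (3.39) rose, as did the replication helicase subunits Mcm5 (from 7.76 to 10.37) and Mcm6 (2.40; adjusted p = 0.121 without ACDiEKO replicate 4), chosen after their values were seen. Camera returned adjusted p = 3.66e-30, and adjusted p = 0.527 with an estimated correlation. ACDiEKO replicate 5 had the lowest cell cycle mean of its group (8.98, against 9.70 to 9.84 in the others; 7.05 to 7.38 in controls) and the highest mean of immune markers (8.65, against 6.86 to 7.37). In the p53 response and apoptosis list, 2 genes rose and 4 fell of 20 (3 rose and 4 fell adjusted over the list alone; median -0.08, adjusted p = 0.682). Polk, a translesion polymerase, Perp, a desmosomal p53 target, and Phlda3 fell (-0.84, -2.10 and -0.70; for Phlda3 adjusted p = 0.0633 without control replicate 3), while the death receptor Fas rose (1.08; adjusted p = 0.0768 without ACDiEKO replicate 4) with Aen (0.31; adjusted p = 0.0988 without ACDiEKO replicate 4). Cdkn1a, the cell cycle inhibitor p21, differed by -0.55 (SE 0.68) and did not pass.

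Of 21 measured genes in the laminar flow and KLF2/KLF4 program, 14 fell and none rose, with a median of -1.37 (0 rose and 14 fell adjusted over the list alone; 7 did not pass). Plpp3, a lipid phosphatase of the endothelial surface, fell by 1.67 (adjusted p = 0.000295), Nos3 by 2.25, Klk10 by 5.04 and Timp3, a metalloproteinase inhibitor, by 1.14 (adjusted p = 0.0653 without ACDiEKO replicate 4). Thbd, the anticoagulant receptor thrombomodulin, differed by -0.07 (adjusted p = 0.613). The list reached adjusted p = 7.66e-08 in camera, and adjusted p = 0.527 with an estimated correlation. Among 11 measured genes reported elsewhere to depend on MEF2, Klf2, Klf4 and Nos3 fell and 8 did not pass (0 rose and 3 fell adjusted over the list alone; median -0.15, camera adjusted p = 0.154, fry adjusted p = 0.0307). Nr4a1, an orphan nuclear receptor in that list, differed by 0.62.

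Genes of the vasoactive signaling list fell in 7 cases and rose in 1 of 17 (1 rose and 7 fell adjusted over the list alone; median -0.22). Gch1, which makes the cofactor of nitric oxide synthase, fell by 2.25, and the calcium-activated potassium channels Kcnn3 and Kcnn4 fell as well, with log2 differences of -2.67 and -2.37, while Edn1 rose by 2.67. As a set, these genes had adjusted p = 0.0109 in camera, and adjusted p = 0.677 with an estimated correlation; the call ended without the 2 controls whose animal numbers lie apart (adjusted p = 0.0835), with the run of animal numbers as a term (0.0639) and with no filter on dim genes (median -0.12, adjusted p = 0.0583). The disturbed flow list rose in 7 and fell in 2 of 14 genes (8 rose and 2 fell adjusted over the list alone; median 0.52). The matricellular gene Ccn2 (3.23), the platelet-derived growth factor Pdgfb (3.05) and the chemokine Cxcl12 (2.45) rose, and Txnip (-0.79) and Sox13 (-1.22) fell. Camera gave adjusted p = 0.0169, adjusted p = 0.677 with an estimated correlation, 0.0526 after median centring, 0.0700 after quantile normalization and 0.0546 with camera on ranks.

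In the leukocyte adhesion and NF-kB list, 6 genes rose and 2 fell of 19 (9 rose and 3 fell adjusted over the list alone; median 0.37). Sele rose by 5.44, the transmembrane chemokine Cxcl16 by 1.82, P-selectin (Selp) by 0.98 and Nfkb2 by 0.50, whereas the NF-kB inhibitor Nfkbia fell by 0.95 and Tnfaip2 by 1.32. The adhesion molecules Vcam1 (0.35) and Icam1 (0.46) and the chemokine Ccl2 (0.25) did not pass. Camera returned adjusted p = 0.00698, adjusted p = 0.677 with an estimated correlation, 0.0596 without the 2 controls whose animal numbers lie apart and 0.0686 with the run of animal numbers as a term. Interferon response genes rose in 2 and fell in 3 of 23 (2 rose and 3 fell adjusted over the list alone; median -0.25, adjusted p = 0.174, and 0.0327 without control replicate 2). Bst2 (1.27) and Ifit2 (0.97; adjusted p = 0.103 without ACDiEKO replicate 4) rose, while the RNA sensor Ifih1 (-1.09), the guanylate-binding Gbp4 (-2.52; adjusted p = 0.0652 without ACDiEKO replicate 4) and Parp14 (-0.44; adjusted p = 0.121 without ACDiEKO replicate 4) fell. Of 14 antigen presentation genes, 1 fell (0 rose and 0 fell adjusted over the list alone; median -0.19, adjusted p = 0.38): the immunoproteasome subunit Psmb10 (-0.55; adjusted p = 0.113 without ACDiEKO replicate 4), next to Psmb9 (-0.50) and Tapbp (-0.41), which did not pass.

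YAP/TAZ targets, genes of the Hippo pathway that respond to mechanical load, rose in 10 and fell in 1 of 16 (10 rose and 1 fell adjusted over the list alone; median 1.05). Ccn2 rose by 3.23, Ccn1 (chosen after its value was seen) by 2.92, Tgfb2 by 4.84, the LIM protein Ajuba by 2.56 and Lhfp by 1.49, while Tead4 fell by 0.79. The list reached adjusted p = 0.000271 in camera, and adjusted p = 0.677 with an estimated correlation. Smooth muscle markers rose in 8 of 14 and fell in none (10 rose and 0 fell adjusted over the list alone; median 0.94). Tagln (3.82), Myl9 (3.68), Acta2 (3.19), Synpo2 (2.15), smoothelin (Smtn, 2.04) and the tropomyosin Tpm2 (0.90; adjusted p = 0.0964 without ACDiEKO replicate 4) rose, and the smooth muscle myosin Myh11 (-0.04), Cnn1 (-0.27) and Mylk (0.43) did not pass; Tpm2, Cnn1 and Mylk were chosen after their values were seen. As a set, these genes had adjusted p = 0.000781 in camera, and adjusted p = 0.677 with an estimated correlation. The marker mean was 8.14 to 9.02 in the control samples and 9.28 to 10.30 in the ACDiEKO samples, so it moved with genotype beside the other lists. In BMP and TGF-beta signaling, 4 genes rose and 2 fell of 17 (5 rose and 3 fell adjusted over the list alone; median 0.04, adjusted p = 0.401). The receptors Acvrl1 (-0.81) and Bmpr2 (-0.41; adjusted p = 0.0586 without ACDiEKO replicate 4) fell, and the coreceptor endoglin (Eng, 1.53), Bmp6 (0.79) and Ltbp2 (0.53; adjusted p = 0.0775 without control replicate 4) rose.

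Arterial identity and Notch genes fell in 12 and rose in 1 of 25 (2 rose and 13 fell adjusted over the list alone; median -0.41). Stmn2 fell by 2.74, the Notch ligand Dll1 by 2.80, the arterial kinase Bmx by 2.14 and the hypoxia factor Epas1 by 0.83. Camera gave adjusted p = 0.000271, and adjusted p = 0.677 with an estimated correlation. Venous identity genes rose in 2 and fell in 4 of 9 (4 rose and 4 fell adjusted over the list alone; median -0.22, mean 0.02, adjusted p = 0.753). Tmem252 (2.33) and Selp rose, and the prostaglandin transporter Slco2a1 (-1.44), the ephrin receptor Ephb4 (-0.73) and Cpe (-0.76; adjusted p = 0.0527 without control replicate 3) fell.

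Endothelial junction genes fell in 6 of 17 and rose in none (0 rose and 8 fell adjusted over the list alone; median -0.39). Cldn5 fell by 3.59, the arterial connexin Gja5 by 2.57, Cldn15 by 1.90, plakoglobin (Jup) by 1.36 and Pecam1 by 0.37, while VE-cadherin (Cdh5, 0.25) did not pass. Camera returned adjusted p = 0.00226, and adjusted p = 0.677 with an estimated correlation. Endothelial markers rose in 3 and fell in 7 of 22 (3 rose and 7 fell adjusted over the list alone; median -0.19, adjusted p = 0.154, with 0.0467 under a stricter filter on dim genes and 0.0341 without ACDiEKO replicate 3). Podxl (-1.60), the angiopoietin receptor Tek (-1.92) and Mmrn2 (-0.96) fell, Emcn rose by 3.72, and von Willebrand factor (Vwf) differed by -0.19. Mechanosensors and ion channels rose in 1 and fell in 3 of 22 (1 rose and 3 fell adjusted over the list alone; median 0.05, mean -0.07, adjusted p = 0.728). The channel Trpv4 fell by 0.88 (adjusted p = 0.0787 without ACDiEKO replicate 4) and the VEGF receptor Kdr rose by 0.96 (adjusted p = 0.0776 without control replicate 2). Lymphatic endothelial markers rose in 1 and fell in 1 of 5 (1 rose and 1 fell adjusted over the list alone; median 0.39, adjusted p = 0.544): Fgl2 fell by 1.29, Nts rose by 1.12 (adjusted p = 0.086 without control replicate 3) and Flt4 differed by 0.39.

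Sprouting and angiogenesis genes rose in 11 and fell in 1 of 21 (14 rose and 3 fell adjusted over the list alone; median 0.76). The laminin chain Lamb1 rose by 3.27, Pdgfb by 3.05, placental growth factor (Pgf) by 2.04, the adhesion molecule Mcam by 2.68 and Col4a2 by 0.76. The list reached adjusted p = 0.000781 in camera, and adjusted p = 0.567 with an estimated correlation. Basement membrane and elastic matrix genes rose in 7 and fell in 4 of 22 (10 rose and 5 fell adjusted over the list alone; median 0.29, adjusted p = 0.228, and 0.0382 with no filter on dim genes). Lamb1 and Sparc (0.64) rose, while Lamb2 (-1.28), the calcification inhibitor Mgp (-1.39) and Fbln2 (-1.44) fell. Endothelial to mesenchymal transition genes rose in 3 and fell in 3 of 16 (4 rose and 4 fell adjusted over the list alone; median -0.37, mean 0.16, adjusted p = 0.735). Tgfb2 and fibronectin (Fn1, 0.46) rose, and Twist1 (-0.99), Fap (-0.42; adjusted p = 0.0616 without control replicate 2) and Tgfb3 (-0.67; adjusted p = 0.0875 without ACDiEKO replicate 4) fell. Of 15 fibrillar collagen and matrix remodeling genes, thrombospondin 1 (Thbs1) rose by 2.36 and Timp3 fell (2 rose and 3 fell adjusted over the list alone; median -0.01, mean 0.05, adjusted p = 0.788), and Adamts1 differed by -1.76. Hemostasis and fibrinolysis genes rose in 4 and fell in 6 of 19 (5 rose and 6 fell adjusted over the list alone; median -0.07, mean 0.10, adjusted p = 1). The urokinase receptor Plaur (2.14) and urokinase itself (Plau, 1.20) rose, and Anxa2 (-0.56) and the ectonucleotidase Nt5e (from 13.22 to 11.22) fell.

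**Figure D3:**
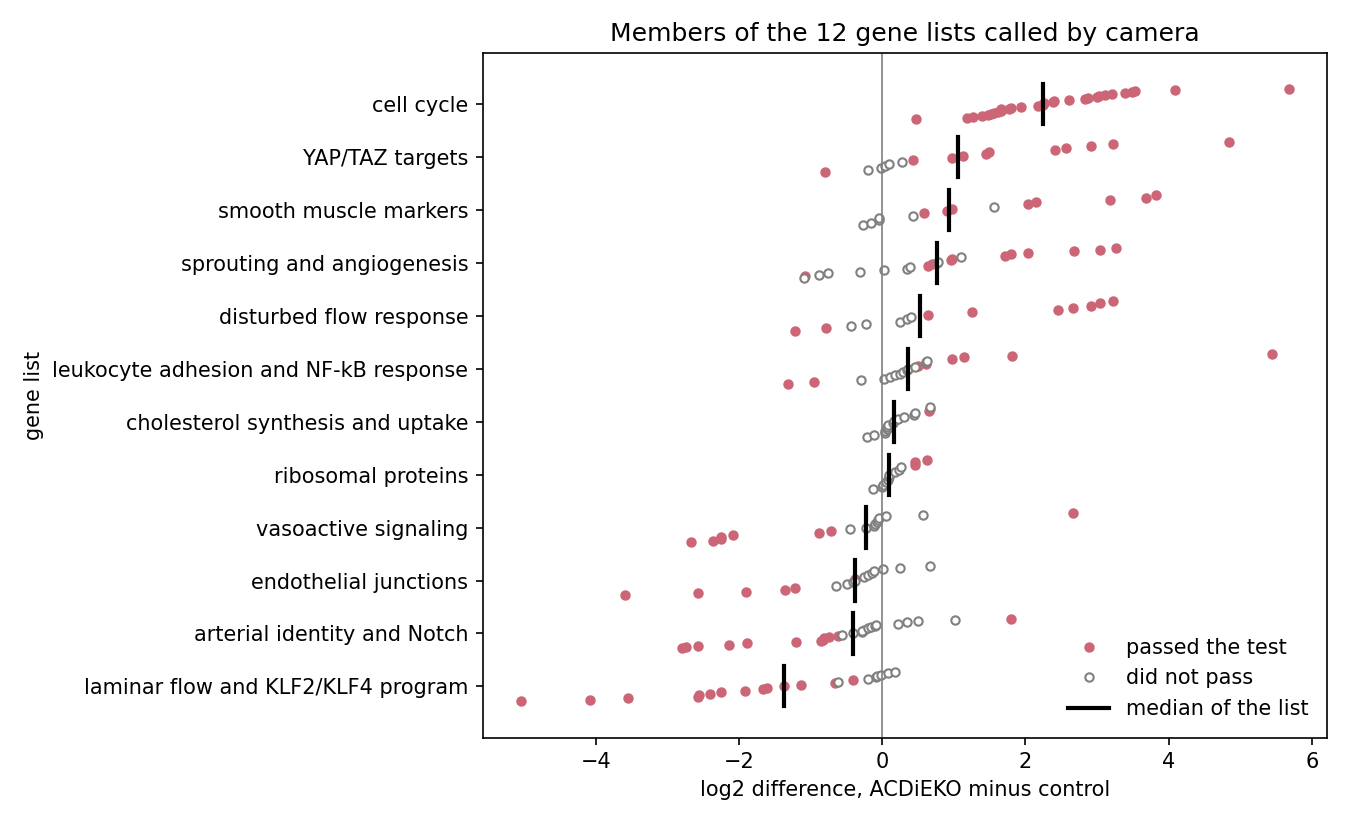
Log2 difference of ACDiEKO minus control (horizontal axis) for each measured member of the 12 gene lists that camera called (vertical axis); filled points passed limma's test, open points did not, and black bars are list medians. Medians ran from -1.37 for the laminar flow and KLF2/KLF4 program to 2.24 for the cell cycle.

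Ribosomal protein genes rose in 3 of 13 and fell in none (3 rose and 0 fell adjusted over the list alone; median 0.10): Rpsa by 0.46, Rplp0 by 0.46 (adjusted p = 0.0576 without control replicate 1) and Rpl27 by 0.63 (adjusted p = 0.0975 without ACDiEKO replicate 4). As a set, these genes had adjusted p = 0.013 in camera, adjusted p = 0.683 with an estimated correlation, 0.138 without the 2 controls whose animal numbers lie apart and 0.157 with the run of animal numbers as a term. Cholesterol synthesis and uptake genes rose in 2 of 16 (5 rose and 0 fell adjusted over the list alone; median 0.16): squalene epoxidase (Sqle) by 0.66 (adjusted p = 0.0674 without control replicate 4) and Idi1 by 0.65 (adjusted p = 0.0941 without control replicate 1), with Hsd17b7 at 0.67. Camera gave adjusted p = 0.0366, and adjusted p = 0.683 with an estimated correlation. It gave 0.146 without control replicate 1 (median 0.087) and 0.0533 without ACDiEKO replicate 3 (median 0.165). It gave 0.0622 without both near-identical ACDiEKO arrays (median 0.128) and 0.698 with a stricter filter on dim genes (median 0.062). Heat shock genes rose in 2 and fell in 1 of 11 (3 rose and 1 fell adjusted over the list alone; median 0.09, adjusted p = 0.233), with the chaperones Hsp90aa1 (0.66) and Hspa4 (0.74) higher and Hspa1a (-0.96) lower. Unfolded protein and integrated stress response genes rose in 4 and fell in 2 of 17 (4 rose and 3 fell adjusted over the list alone; median 0.12, adjusted p = 0.401). Edem1 (0.54), Sdf2l1 (0.70), Creld2 (0.81; adjusted p = 0.0562 without ACDiEKO replicate 4) and the transcription factor Atf4 (0.51; adjusted p = 0.082 without ACDiEKO replicate 4) rose, and Dnajb9 (-0.80) fell. Immediate early genes rose in 3 and fell in 1 of 17 (3 rose and 2 fell adjusted over the list alone; median -0.09, mean 0.10, adjusted p = 1). The growth regulator Myc rose from 7.94 to 10.94, Fosl2 by 0.81 and Atf3 by 0.68 (adjusted p = 0.101 without control replicate 4), and Nr4a2 fell by 0.67 (adjusted p = 0.0803 without ACDiEKO replicate 4).

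Metabolic lists carried few calls. Glycolysis had 1 gene that rose, the glucose transporter Slc2a1 (0.89; adjusted p = 0.064 without ACDiEKO replicate 4), and 1 that fell, Pfkfb3 (-0.47; adjusted p = 0.0514 without control replicate 4), of 15 (1 rose and 1 fell adjusted over the list alone; median -0.09, mean 0.03, adjusted p = 0.718), and Pfkp differed by 0.72. NRF2 and oxidative stress genes fell in 2 of 15 (0 rose and 2 fell adjusted over the list alone; median -0.15, adjusted p = 0.423): Gstm1 (-0.75; adjusted p = 0.0621 without ACDiEKO replicate 4) and the ferritin chain Fth1 (-0.35; adjusted p = 0.106 without ACDiEKO replicate 4), with Txnrd1 at 0.41. None of 25 oxidative phosphorylation genes passed limma, and 0 rose and 0 fell adjusted over the list alone (median -0.10, camera adjusted p = 0.544). Without control replicate 1 the list median was -0.23 (camera adjusted p = 0.0159). Ppargc1a differed by -0.79, Cox4i1 by -0.16 and Sdha by -0.28. None of 19 fatty acid handling genes passed limma either (0 rose and 0 fell adjusted over the list alone; median -0.22, adjusted p = 0.718), with Plin2 at -0.89, Fabp5 at -0.55 and Acsl5 at 0.25.

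Markers of other cell types that the flush could carry were read in the same way. Of the fibroblast markers, Pi16 is also a member of the laminar flow list. Fibroblast markers rose in 1 and fell in 2 of 12 (2 rose and 5 fell adjusted over the list alone; median -0.03, adjusted p = 0.428): Clec3b (-1.60) and Pi16 (-2.41) fell and Serpinf1 rose (0.77; adjusted p = 0.107 without ACDiEKO replicate 4). Striated muscle markers rose in 1 of 5 (1 rose and 0 fell adjusted over the list alone; median 0.19, adjusted p = 0.399), the skeletal actin Acta1 (0.91), with Tnnt2 at 0.29 and Mb at -0.23. No gene passed limma among 13 macrophage markers (median 0.32, adjusted p = 0.169, with 0.0397 with no filter on dim genes, 0.0327 without control replicate 2 and 0.0485 without ACDiEKO replicate 4), such as Mertk (0.83), Cd68 (0.81) and Csf1r (0.44). The same held for 8 neutrophil markers (median 0.65, adjusted p = 0.203, and 0.0485 without ACDiEKO replicate 4), with Retnlg at 1.25, S100a8 at 1.34 and S100a9 at 0.98, and for 6 lymphocyte markers (median 0.33, adjusted p = 0.524), with Nkg7 at 0.23, Ighm at 0.71 and Cd3d at 0.45. It also held for 5 platelet markers (median 0.13, adjusted p = 0.713), with Gp9 at -0.32, Itga2b at 0.13 and Pf4 at 1.05, and for 11 adipocyte markers (median -0.36, adjusted p = 0.71), with Ucp1 at -2.37, Retn at 0.98 and Cox8b at -1.24. Mesothelial markers had a median of 1.15 over 7 genes with 0 calls (adjusted p = 0.0761, with 0.0433 without control replicate 4 and 0.0254 without ACDiEKO replicate 3), with Krt18 at 1.99, Upk1b at 1.72 and Lrrn4 at 1.04. Their mean was 10.80 in ACDiEKO replicate 4 and 10.65 in ACDiEKO replicate 5, and lower in each of the other 7 arrays (8.43 to 8.65 in ACDiEKO replicates 1 to 3). The mesothelial list was called with no filter on dim genes (adjusted p = 0.00612), with camera on ranks (0.0365) and without both near-identical ACDiEKO arrays (0.00894). Only 2 erythrocyte markers were bright enough to test, Slc4a1 (0.10) and Alas2 (-0.18), and no Schwann cell marker was, so camera was not run on either list. Adjusted over the list alone, 0 genes passed in the macrophage, neutrophil, lymphocyte, platelet, adipocyte and mesothelial lists. The transcription factor Dach1, fixed for reporting before the data were examined, differed by 0.04 (adjusted p = 0.765).

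Camera called 12 of 42 lists at a preset correlation between genes of 0.01, 8 upwards and 4 downwards, and none of the 12 kept its call with an estimated correlation (adjusted p = 0.527 to 0.683). Fry, which asks whether a list's genes move on balance in a single direction without comparing them with other genes, also called 12, of which 11 were the same; it added the genes reported to depend on MEF2 (adjusted p = 0.0307) and left out the cholesterol list (0.121). With the smooth muscle marker mean as a covariate, 4 of the 12 lists kept their call (cell cycle, laminar flow, sprouting and cholesterol), 7 lost it (YAP/TAZ targets, arterial identity, junctions, disturbed flow, leukocyte adhesion, vasoactive signaling and ribosomal proteins) and the smooth muscle list changed sign. Among other divisions of the 8 samples into groups of 4, as many as 17 lists were called at the preset correlation. The called lists share members, so they are not 12 separate findings. Nos3 lies in the laminar flow and vasoactive lists, and Gja5 in the laminar flow, arterial and junction lists. The disturbed flow list shares Ccn1 and Ccn2 with YAP/TAZ targets, Edn1 with vasoactive signaling and Pdgfb with sprouting. Klf2, Klf4 and Nos3, the MEF2-dependent genes that fell, are also laminar flow members.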

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

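Tests of smooth muscle, endothelial and immune RNA, of scaling and of near-identical kallikreins were chosen after the result was seen. The test of genes beside the kallikreins was also chosen after their falls were seen. Splits of the arrays were planned. The splits made after averaging the near-identical ACDiEKO arrays were not, since that averaging was chosen after seeing the data. Of 498 groups of 4 samples looked at, 26 held a sample far from the other 3 by Dixon's critical value (5.22%, where chance gives about 5%).

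ACDiEKO replicate 5 held 9 of them: Cd3d at 8.65 (others 5.72 to 6.18), Csf1r at 7.08 (6.21 to 6.33), Ighm at 11.18 (7.60 to 8.19), Retn at 9.72 (6.73 to 7.22), Gp9 at 7.82 (7.73 to 7.74), Kif11 at 8.94 (9.89 to 9.99), Mki67 at 13.12 (13.88 to 14.00), the cell cycle mean at 8.98 (9.70 to 9.84) and the NRF2 and oxidative stress mean at 10.55 (10.16 to 10.22). ACDiEKO replicate 4 was low for Cox8b (7.27, others 11.30 to 12.02), Ucp1 (7.53, 12.42 to 13.33) and the BMP and TGF-beta mean (10.54, 10.71 to 10.71). The averaged ACDiEKO replicates 1 and 2 stood apart for Acsl5 (12.55, others 12.28 to 12.30) and Klk1b22 (10.01, 6.02 to 6.32), and ACDiEKO replicate 3 for Hdac9 (6.58, others 6.61 to 6.61).

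Among controls, replicate 1 stood apart for Bmx (14.41, others 14.66 to 14.70), Klk1b22 (8.21, 13.22 to 13.88) and Lhfp (9.18, 8.48 to 8.54). Control replicate 2 stood apart for Hdac9 (6.69, others 6.60 to 6.61), Kif11 (5.75, 6.25 to 6.36) and Nup160 (11.04, 11.47 to 11.54). Control replicate 3 stood apart for Fgl2 (6.77, others 7.37 to 7.46), Gja5 (15.74, 15.20 to 15.27) and Tek (15.84, 15.16 to 15.24), and control replicate 4 for Dach1 (6.44, others 6.57 to 6.58) and Mmrn2 (15.26, 15.70 to 15.78).

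The real grouping gave 2666 genes, and the highest of the other 34 splits of the 8 samples gave 2. Only 1 of 35 splits reached the real count, the smallest share that 8 samples allow, which argues against chance without excluding it. For transcript clusters the real count was 2824 and the highest other 0 (1 of 35), which argues against chance to the same degree. For gene lists the real count was 12, the highest other 17, and 14 of 35 splits gave as many, so chance cannot be excluded for the number of lists. With each of the 9 arrays as a sample, 100 splits were drawn: genes 3710 against 2144 (1 of 100), transcript clusters 4692 against 16 (1 of 100) and lists 12 against 18 (31 of 100). The 2144 came from ACDiEKO replicates 1 to 4 against all other arrays, which is the real grouping with ACDiEKO replicate 5 moved to the controls. The next highest count, 1317, moved ACDiEKO replicate 3 in the same way. Both divisions keep the near-identical pair together, and whether that raised the counts was not tested.

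Of 14 smooth muscle markers, 8 were higher in ACDiEKO and 6 did not pass (Myh11 -0.04, Cnn1 -0.27), and the list lost its call with an estimated correlation (adjusted p = 0.677). Smooth muscle markers rose by 1.58 more than fibroblast markers, with a lower 95% limit of 0.598. The fibroblast marker Pi16 is also in the laminar flow list, and its fall widens this gap, which was not computed without it. This argues only against a lower share of endothelial RNA that raises all other cell types alike. A lower share made up by smooth muscle RNA was not tested by this gap. Smooth muscle RNA carried into the flush stays open. A contractile gene counted as clear of background with a group mean at least 2 log2 units above the table median of 6.165. Of 5 such genes only 1, Cnn1, had an upper limit below the list median of 0.94. The other contractile genes that did not pass, Myh11 and Mylk, had no group mean that high. A change of the endothelial cells themselves by the deletion or the active recombinase may also raise these genes. These data cannot tell these explanations apart.

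Cell cycle genes were higher in ACDiEKO. The rise of the cell cycle mean exceeded that of immune markers by 1.87, with a lower 95% limit of 0.330. This argues only against immune cells in the flush that raise both means alike. Immune cells that raise cell cycle genes more than these markers were not tested by this gap. ACDiEKO replicate 5 had the highest immune mean and the lowest cell cycle mean. The lower of the list's medians under the other scalings was 2.30, with 32 of 32 genes called. Array medians lay between 6.13 and 6.23 before, so these scalings could hardly have removed a rise of this size. The check therefore shows only that the rise does not depend on them. Cell division caused by loss of MEF2 may explain the rise, a hypothesis that no test here addressed. Loss of MEF2 and the active recombinase cannot be told apart, since controls lacked the recombinase.

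All 16 tested kallikreins were lower in ACDiEKO. Near-identical copies read by the same probes cannot explain the 4 outside the Klk1 and Klk1b group, whose median was -2.79. For Klk1 and Klk1b, all 12 had an upper 95% limit below 0, but their intervals share no common value (Klk1 -5.90 to -3.58, Klk1b7-ps -1.22 to -0.78), as equal reading of a single transcript would need. Probes shared in part, which read a copy at unequal strength, stay open there, and Klk1b7-ps was chosen after its values were seen. Of 20 tested neighbours, 2 were lower (10%, upper limit 31.7%, one-sided Fisher's exact p = 0.437), against 7.33% of all tested genes. This argues only against a chromosome segment, differing between the groups, that lowers most of its neighbours. A segment confined to the cluster is not decided, since only 1 other tested gene lies between the kallikreins. Regulation of the cluster by MEF2 or by KLF2 and KLF4 may explain the falls, a hypothesis that was not tested.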

How the results depend on the processing

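All alternatives were planned except all 9 arrays as samples and the fit without both near-identical ACDiEKO arrays, which were chosen after seeing the data. Where a value moved, the cause was not tested unless the alternative has fewer samples or another threshold by construction. The main counts were 2666 genes (1463 higher, 1203 lower), 2824 transcript clusters and 12 lists. The median of all genes moved from -0.03 to 0.03 under both scalings.

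At an adjusted p under 0.10, 4045 genes (1952 lower) and 4882 clusters passed, and with a log2 difference of at least 1, 874 genes (502 higher, 372 lower) and 1277 clusters. Without the 2 controls of distant animal numbers, which leaves 2 controls, 1127 genes (634 higher, 493 lower) and 58 clusters passed, and with the run of animal numbers as a term, 1692 genes (934 higher, 758 lower) and 1234 clusters. Both fits take the genotype difference from the other 2 controls alone. With the 9 arrays as samples 4692 clusters passed. Without both near-identical arrays 801 genes were lower and 1260 clusters passed. With the replicate block, 2351 genes and 1710 clusters passed, but same-number correlations of -0.145 to 0.0413 give the block no basis. The ribosomal list lost its call with the block (median 0.087, adjusted p = 0.0772). Leaving out 1 array at a time gave 1680 to 2701 genes, 948 to 1466 higher, 732 to 1235 lower, 1134 to 2786 clusters and 12 to 14 lists; the lowest gene and cluster counts came without ACDiEKO replicate 4. Clusters were also fewer without control replicate 2 (1880), control replicate 3 (1304) and control replicate 4 (1326).

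The mean of all smooth muscle markers, dim ones included, was used as a covariate. With it, 0 genes passed in limma (0 higher, 0 lower) and 7 lists were called. Of the 12 lists, 4 kept their call and 7 lost it. Those lost included YAP/TAZ targets (median 0.15), disturbed flow (0.15), arterial identity (-0.18) and junctions (-0.17). Macrophage (0.77) and neutrophil (2.28) markers and oxidative phosphorylation gained a call, the last with its sign reversed (0.43, camera adjusted p = 0.00311). A second fit used the mean of the 14 tested markers, and 1397 genes had an unadjusted p under 0.05 in limma. That mean follows genotype (76.1% of its variance lies between groups). Both a larger median SE (0.120 to 0.242) and smaller differences weaken calls there. Acta2 went from 3.19 (SE 0.60) to 0.60 (SE 0.69), Sele from 5.44 (0.89) to 2.14 (1.31) and Klf4 from -4.09 (0.47) to -2.22 (0.63). Klk10 went from -5.04 (0.58) to -2.68 (0.77), Tgfb2 from 4.84 (0.49) to 2.68 (0.53) and Mki67 from 5.68 (0.22) to 5.38 (0.46). Of 2666 genes, 2601 kept their sign in this second fit. In the fit that included dim markers, Atf4 became -0.084, Serpinf1 -0.16, Tpm2 -0.13 and the smooth muscle list -0.073. Mef2d rose by 0.31 (adjusted p = 0.0375) after quantile normalization. With an estimated correlation, 0 of 12 lists kept their call in camera, and fry called 12. Of 152 named genes called, 117 were called in all 9 fits that left out 1 array. Leaving out ACDiEKO replicate 1 or 2 kept its near-identical partner, so those fits could hardly lose a call. Without both near-identical arrays, 27 of the 152 lost their call. Of the 152, 63 lost their call without the 2 controls of distant animal numbers and 35 with the run of animal numbers as a term. With no filter 27 lost it, and with the smooth muscle covariate that included dim markers 149 did, with 3 more reversed.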

Other observations

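Families of genes that share a symbol stem were tested after their values were seen, each of 383 families with at least 5 tested genes for a surplus of higher or lower genes (766 tests, hypergeometric, Benjamini-Hochberg), and 9 passed. Members of a stem need not share a function. Higher were 14 of 24 genes with the stem Kif (mostly kinesin motors; Kif23 2.72, Kif15 2.28, with Kif13a among 3 lower at -0.88; adjusted p = 6.05e-07), 6 of 7 with the stem Cdca (Cdca8 1.49, Cdca2 1.37; adjusted p = 0.000618) and 6 of 8 with the stem Mcm (Mcm5 from 7.76 to 10.37, Mcm6 2.40, the latter with adjusted p = 0.121 without ACDiEKO replicate 4; adjusted p = 0.00152). Also higher were 6 of 8 genes with the stem Cct, which include a pseudogene (Cct3 0.94, Cct8 0.65; adjusted p = 0.00152), 4 of 5 with the stem Ipo (Ipo5 1.19, Ipo9 0.75; adjusted p = 0.0280) and 7 of 15 with the stem Nup, with 1 lower (Nup43 1.05, Nup93 1.00, Nup160 -0.49 with adjusted p = 0.106 without control replicate 4; adjusted p = 0.0164). Lower were 9 of 13 Krüppel-like factors (Klf12 -2.41, Klf10 -1.20, Klf9 -1.15 with adjusted p = 0.055 without ACDiEKO replicate 4; adjusted p = 8.31e-06), 16 of 16 kallikreins (Klk8 -2.82, Klk11 -2.76, Klk9 -0.65, Klk1b22 -5.15 with adjusted p = 0.117 without ACDiEKO replicate 4; adjusted p = 4.89e-16) and 4 of 6 Hoxa genes (Hoxa2 -0.83, Hoxa6 -0.81 with adjusted p = 0.0731 without ACDiEKO replicate 4; adjusted p = 0.0326). In Kif15 and Cdca2 (controls) and Klk9 (ACDiEKO) a group mean lay below the filter value of 6.165, so their differences may be understated. Genes of a family are not independent, so these p-values are a guide only.

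Among the 12 called lists, 2, cell cycle and the laminar flow and KLF2/KLF4 program, had a smaller camera p under the real grouping than under each of the other 34 splits of the 8 samples, a comparison made after the result was seen. Of the 35 splits, 10 gave the cholesterol list as small a p as the real one and 7 the leukocyte adhesion list. The macrophage marker Lyz2, chosen after its value was seen, differed by 1.43 and did not pass.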
